A study of Mus musculus with 8 samples.

How the data were processed

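RNA from chondrocytes, the cells that form cartilage, was measured on 8 Affymetrix arrays. Per the labels, rib cages of FVB mouse embryos at embryonic day 18.5 were digested with collagenase and trypsin, the cells were passed through a strainer and stored in Trizol, and total RNA was labelled with biotin. Per the labels, embryos of 4 litters were sorted by genotype into controls and Hoxc8 transgenics, so that each litter gave 1 control and 1 transgenic sample. The litter numbers are 168, 170, 173 and 174 and stand for replicates 1, 2, 3 and 4 of both genotypes, called litters 1 to 4 here. The labels do not say how many embryos or which sexes went into a sample.

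The deposited values are intensity signals on a linear scale, 1 per probe set and array. The submitters' processing notes name MAS5, whose version is not given in the sources used here. On every array the mean of the deposited signals, after trimming 2% at each end, was 500, which means that each array had been scaled to the same target before deposit. The smallest signals on the arrays lay between 0.105 and 0.26. Detection calls were not used here.

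Of the 45101 probe sets, 34945 had 1 gene symbol in the platform annotation of 2016, 932 had several and 9160 had none, besides 64 Affymetrix control probe sets. The Entrez IDs of 34741 single-symbol probe sets were found in a RefSeq gene table, assembly GRCm38.p6, and 204 were not; the table changed 0 symbols. Genes were named only from probe sets with 1 symbol, and no coordinates are given because the sources used here name no genome build for the array.

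Signals were transformed as log2(signal + 22.2), the offset being the 20th percentile of the deposited values, so that fold changes of dim genes are understated. Probe sets with a mean signal of at least 110, the median of the probe set means, were tested, which left 22519 probe sets and 10989 genes. A gene was represented by its probe set with the highest mean signal. The genotypes were compared with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, all 8 arrays, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. No further normalization was applied, since MAS5 had scaled the arrays. Intervals are 95% confidence intervals from the moderated fit. Unless a block is named, intervals and SEs leave out the pairing by litter, so they also hold differences between litters. Exact two-sided permutation tests over the 70 assignments of 4 and 4 arrays served for Hoxc8 and for the quality measures, and their smallest possible p is 0.0286.

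Gene lists were written before the data were examined: 38 lists with 1034 genes, of which 96 had no probe set with a single symbol. The 36 lists with at least 5 tested members were compared with camera, a competitive test in limma, at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry, directional and mixed, were run beside it. Many genes belong to more than 1 list, and markers of other cell types can also be expressed by chondrocytes.

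The rule for named genes was fixed before the data were examined. It takes Hoxc8, then the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with 4 same-signed litter differences, filled up by smallest unadjusted p where fewer pass, then up to 4 members of each list described, then the Gapdh and beta-actin control probe sets. The lists described with named members, and the limit of 2 members in each (4 for the lists of neutrophil and sex-linked genes), were chosen after a first look at the list results.

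The replicate numbers pair the samples because the labels tie each number to a litter. The deviations of same-numbered arrays from their group means correlated at 0.0251, 0.434, 0.376 and 0.379 for replicates 1 to 4 across probe sets. The highest correlations of these control arrays with a transgenic array of another number were 0.063, 0.0133, 0.0303 and 0.00416. The pairing was thus not seen for replicate 1. The fit without the litter had been set as the main one, and the fit with litter as a block is given where it changes a call or a count of calls.

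Alternatives set before the data were examined were the litter as a block, other offsets, no filter and a stricter filter, quantile normalization, median centring, eBayes without trend and with robust fitting, array weights, other treatments of several probe sets per gene, leaving out each array or litter, an unmoderated equal-variance test, and other list tests. Xist signal as a covariate, alone and with the litter as a block, and camera with an estimated correlation and the litter as a block were added after seeing the data. Litter differences were tested, also after seeing the data, with limma's moderated F-test with genotype in the model.

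The steps were tested on simulated data with the real probe set means, litter effects and residual spread, over 22519 probe sets with 200 changed. For transgenic against control, without the litter as a block, 11 of 50 probe sets changed 1.5-fold, 31 of 50 changed 2-fold, 43 of 50 changed 3-fold and 47 of 50 changed 4-fold were recovered, with 0 false calls. With the block, 23, 32, 44 and 45 of 50 were recovered, with 3 false calls. A simulated shift of 0.3 log2 in the cartilage matrix list was recovered with adjusted p of 2.31e-37, and of 0.000975 with an estimated correlation. All its members were shifted alike and noise was drawn independently for each probe set. In the real data the estimated correlation of this list was 0.16 with litter as a block. How well shifts are recovered in lists whose members vary together was thus not simulated. The simulated data for the litter F-test held no litter effects besides a 2-fold rise of 200 probe sets in litter 2. For this 1 litter against the other 3, 49 of the 200 were recovered by the F-test, with 2 false calls. In the real data 2027 probe sets passed that test, so this recovery does not describe it. With arrays, the number of samples limits the precision.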

Results

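Rib chondrocytes of mouse embryos at stage E18.5 were profiled on 8 arrays, 4 from control embryos and 4 from embryos carrying a Hoxc8 transgene. Each of 4 litters gave 1 sample of each genotype. Median signals of the arrays lay between 107 and 121, and Spearman correlations between arrays across probe sets lay between 0.924 and 0.943. The number of arrays limits the precision of every value.

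The comparison asks which transcripts differ when Hoxc8, a homeobox gene that acts in the patterning of the trunk skeleton, is overexpressed in chondrocytes. Hoxc8 itself gave a mean signal of 3519 ± 501 (SD, n = 4) in control samples and 3885 ± 369 (SD, n = 4) in transgenic samples. The fitted difference was 0.15 log2 (SE 0.12), with a 95% interval from -0.11 to 0.41, that is 0.924-fold to 1.33-fold, and the exact permutation p was 0.229. The ratio of transgenic to control was 0.996, 1.11, 1.01 and 1.35 in litters 1, 2, 3 and 4. These values leave out the pairing by litter. With litter as a block the SE was 0.08 (limma, unadjusted p = 0.0994, adjusted p = 0.9998), so the difference was not called in either fit. Whether this probe set covers the part of the gene that the transgene carries is not given in the sources used here, so it checks the genotype labels little.

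**Figure D1:**
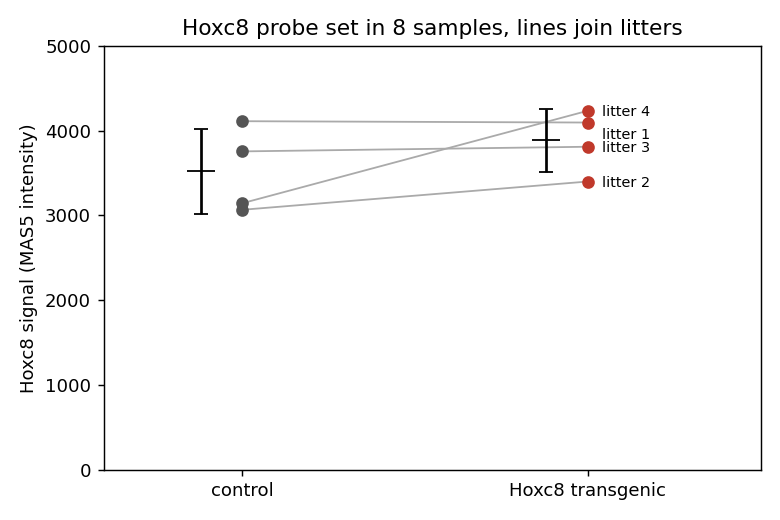
Hoxc8 signal (MAS5 intensity, vertical axis) in the 4 control and 4 transgenic samples. Points are arrays, grey lines join the samples of a litter, and black bars show mean ± SD, 3519 ± 501 in control and 3885 ± 369 in transgenic samples, which overlap.

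No gene passed the test between genotypes, and the genes below are those with the smallest unadjusted p among genes with 4 same-signed litter differences. Pidd1, which encodes a protein of the PIDDosome, had a mean signal of 63.4 ± 35.9 (SD, n = 4) in control and 162 ± 59.2 in transgenic samples, a fitted difference of 1.13 log2 (SE 0.35). For 2900076A07Rik the means were 68.6 ± 23.4 and 152 ± 37.9 (0.95 log2, SE 0.26), and for Tubb4a, a beta-tubulin gene, 83.1 ± 6.84 and 152 ± 39.5 (0.70 log2, SE 0.23). Pop1, a subunit gene of RNase P, stood at 0.79 log2, Stk11ip at 0.64, Shld2, of the shieldin complex in DNA repair, at 0.56, Pou5f2 at 0.54, Brap at 0.50, Nle1, which acts in ribosome assembly, at 0.45, and Acot8, a peroxisomal thioesterase gene, at 0.42.

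Among genes with a lower fitted level in transgenic samples, Kctd1 had means of 158 ± 18.6 (SD, n = 4) in control and 76.3 ± 18.8 in transgenic samples, a difference of -0.89 log2 (SE 0.22). For Frs3, an adaptor of FGF receptors, the means were 180 ± 39.8 and 99.4 ± 15.96 (-0.72 log2, SE 0.22), and for Specc1 259 ± 24.4 and 156 ± 39.2 (-0.68 log2, SE 0.19). The transgenic means of Kctd1 and Frs3 lay under the filter signal of 110. Among the genes with a higher fitted level, so did the control means of Pidd1, 2900076A07Rik, Tubb4a, Pop1 (85.5) and Stk11ip (87.9). Each of these genes passed the filter, set on the mean of all arrays, only through the genotype with the higher signal. Mrln, the gene of a muscle micropeptide that acts on the calcium pump, stood at -0.53 log2 and Dok7, which acts at the neuromuscular junction, at -0.47. Sebox stood at -0.71 log2, Mchr1 at -0.64, Vps13d at -0.47, Dcaf15 at -0.45 and Dguok, a mitochondrial nucleoside kinase gene, at -0.37. Another probe set of Mchr1 stood at 0.47 log2, the opposite sign. None of these 20 genes passed (limma, smallest adjusted p 0.9999).

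**Figure D2:**
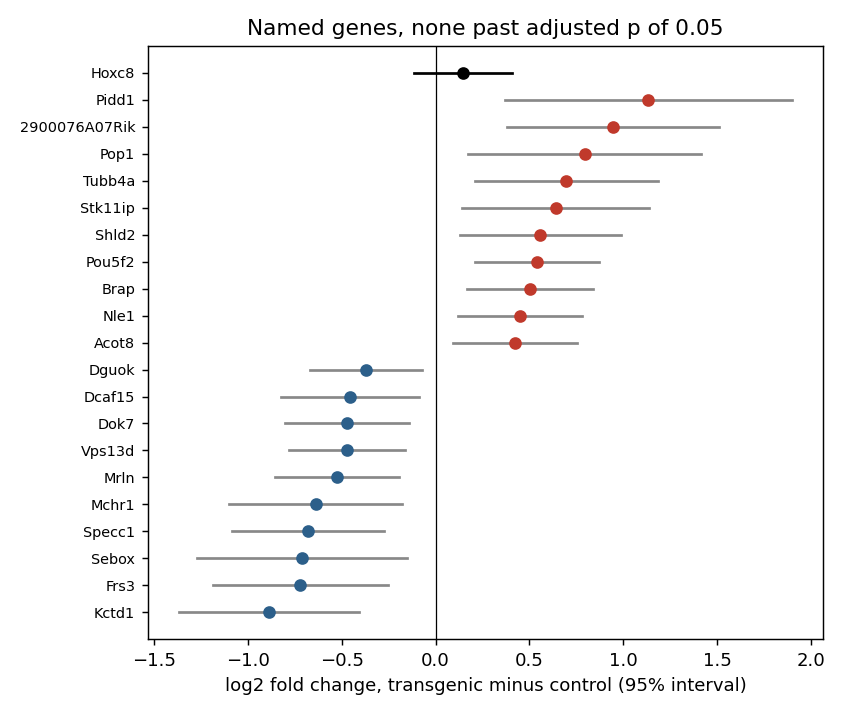
Fitted log2 fold changes (horizontal axis, transgenic minus control) with 95% intervals for Hoxc8 and 20 named genes, 10 with a positive and 10 with a negative difference. Hoxc8 stands at 0.15; Pidd1 has the highest value of the plot, 1.13, and Kctd1 the lowest, -0.89.

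By limma, 0 of 22519 probe sets and 0 of 10989 genes passed an adjusted p of 0.05 in either direction; 246 probe sets had an unadjusted p under 0.05, 124 with a positive and 122 with a negative difference, where 1126 would arise by chance. With litter as a block 0 probe sets passed and 752 had an unadjusted p under 0.05, and an unmoderated equal-variance test gave 0 and 386. The smallest adjusted p was 0.9999 in limma and 0.989 with the block. The median half-width of the 95% intervals was 0.36 log2, and for 97.4% of probe sets the interval lay within 2-fold in either direction, for 75.03% within 1.5-fold. A fitted change above 2-fold was seen for 7 probe sets. Differences had the same sign in all 4 litters for 1175 genes (10.7%), where chance gives 12.5%.

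Lists of cartilage genes gave medians close to 0. Col2a1, the main fibrillar collagen of cartilage, had means of 47268 ± 10892 (SD, n = 4) in control and 40992 ± 2737 in transgenic samples (-0.18 log2, SE 0.13), and Matn1, a cartilage matrilin, 4264 ± 835 and 3548 ± 474 (-0.25 log2, SE 0.14). Of the 28 cartilage matrix genes tested, 9 had a positive and 19 a negative difference, with a median of -0.03 log2 (camera adjusted p = 0.732). Of 24 genes of proteoglycan synthesis and sulphation, 17 had a positive difference, with a median of 0.04 log2 (adjusted p = 0.720). Papss2, which makes the sulphate donor of proteoglycans, had means of 15468 ± 1184 (SD, n = 4) in control and 17857 ± 1342 in transgenic samples (0.21 log2, SE 0.09), and Chsy1, a chondroitin synthase gene, stood at 0.14 log2. For 26 chondrocyte transcription factors the median was -0.02 log2 (adjusted p = 0.704), with Zfp219 at -0.40 and Sox5, a partner of Sox9, at -0.20; 2 of the 5 tested probe sets of Sox5 had the opposite sign, up to 0.56.

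Genes of the growth plate zones gave medians close to 0. The median was -0.02 log2 over 21 hypertrophic chondrocyte genes (adjusted p = 0.832), -0.05 over 16 genes of resting and periarticular chondrocytes (adjusted p = 0.832) and -0.03 over 26 matrix proteases and inhibitors (adjusted p = 0.832). Mmp13, a collagenase gene of late hypertrophic cartilage, had means of 131 ± 43.7 (SD, n = 4) in control and 190 ± 96.6 in transgenic samples (0.42 log2, SE 0.31). Dlx5 stood at -0.27, Apoe at 0.41, Sfrp5 at 0.25 and Adamts9 at -0.24 log2, the last with 1 of 3 probe sets of the opposite sign.

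Genes of the cell cycle were also compared. The 33 genes of G1 and S phase had a median of -0.01 log2 and the 35 of G2 and M phase 0.01 (adjusted p = 0.832 each), with Cdc45 at -0.21, Ccne1 at 0.15, Kif23 at -0.17 (another of its probe sets had the opposite sign) and Ect2 at 0.15. Of 16 cell cycle inhibitors, 15 had a positive difference, with a median of 0.07 log2 and an adjusted p of 0.377; Gadd45a stood at 0.21 and Mxd4 at 0.14. With litter as a block this list passed, higher in transgenic samples (adjusted p = 0.015), and its call was lost with an estimated correlation (adjusted p = 0.929), without litter 1 (adjusted p = 0.0843) and without litter 3 (adjusted p = 0.361).

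Signalling genes gave medians between -0.05 and 0.00 log2. They were 0.00 over 47 genes of BMP and TGF-beta signalling (adjusted p = 0.832), -0.01 over 18 of hedgehog and PTHrP signalling (adjusted p = 0.832), -0.03 over 44 of Wnt signalling (adjusted p = 0.832) and -0.05 over 17 of IGF signalling (adjusted p = 0.720). Bmp2 stood at -0.32 log2 and Bmp7 at -0.60 (SE 0.42), with another probe set of Bmp7 at -0.06. The Wnt pathway genes Kremen1, a Dickkopf receptor gene, and Rspo3, an R-spondin gene, stood at 0.31 and 0.23. Disp1 and Smo of the hedgehog pathway stood at 0.21 and 0.14. Pappa2 and Htra1 stood at -0.19 and 0.17, the last with another probe set of the opposite sign. Medians were 0.00 over 15 genes of FGF signalling (adjusted p = 0.934) and 0.00 over 18 of Notch signalling (adjusted p = 0.934).

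The 15 Hox genes tested had a median of -0.02 log2 (adjusted p = 0.934), with Hoxd8 at -0.26 and Hoxb3 at 0.20, and 8 Hox cofactors a median of 0.00 (adjusted p = 0.832). The other biology lists stood at 0.03 for hypoxia and glycolysis (29 genes, adjusted p = 0.720), 0.03 for the unfolded protein response (27, 0.832), -0.03 for the interferon response (14, 0.832), -0.01 for cytosolic ribosomal proteins (36, 0.832), 0.00 for oxidative phosphorylation (47, 0.991) and -0.01 for cytoskeleton and focal adhesion (29, 0.832).

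Markers of other cell types that a digested rib cage can hold were compared where they passed the signal filter. Medians were -0.03 log2 over 31 skeletal muscle genes, with Myh3 at 0.56 and Casq2 at 0.37; -0.05 over 25 genes of perichondrium and fibroblasts, with Fbln5 at -0.27 and Aspn at 0.20, another probe set of Aspn having the opposite sign; -0.07 over 10 osteoblast genes, with Ifitm5 at -0.39; and -0.02 over 13 macrophage genes, with Lyz2 at -0.25 and Csf1r at -0.24, another probe set of Csf1r standing at 0.86. Their adjusted p were 0.832, 0.532, 0.720 and 0.704. Medians were -0.03 for osteoclasts (8 genes, adjusted p = 0.934), -0.03 for mast and lymphoid cells (6, 0.832), 0.00 for endothelial cells (20, 0.832), -0.03 for pericytes and smooth muscle (12, 0.720), -0.11 for adipocytes (6, 0.704), -0.01 for neurons and Schwann cells (9, 0.934) and 0.15 for keratinocytes and other epithelium (6, 0.832).

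Of 11 erythroid genes, 10 had a negative difference, with a median of -0.16 log2 and the smallest list adjusted p, 0.275; Add2 stood at -0.39 and Rhd at 0.34. With litter as a block the erythroid list passed, lower in transgenic samples (adjusted p = 0.00676), and the call was lost with an estimated correlation (adjusted p = 0.929) and without litter 1 (adjusted p = 0.213). The 4 neutrophil genes tested all had negative differences, and the list was too short for camera. S100a9 stood at -0.42, S100a8 at -0.37, Lcn2 at -0.28 and Ngp at -0.14 log2; adjusted over the list alone, 0 passed, and 2, S100a9 and S100a8, passed with the litter as a block.

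Of 33 genes induced when tissue is dissociated, 26 had a positive difference, with a median of 0.06 log2 and an adjusted p of 0.351. Il6 had means of 203 ± 112 (SD, n = 4) in control and 308 ± 102 in transgenic samples (0.62 log2, SE 0.28). For Cxcl1 they were 994 ± 540 and 1261 ± 409 (0.41 log2, SE 0.29). The SEs were 0.16 for Il6 and 0.11 for Cxcl1 with litter as a block, and neither gene was called (limma adjusted p = 0.9998 each). With litter as a block the list passed, higher in transgenic samples (adjusted p = 0.00041), and the call was lost with an estimated correlation (adjusted p = 0.929) and without litter 3 (adjusted p = 0.502). Of the sex-linked genes, Xist, expressed in female cells, had means of 10366 ± 3274 (SD, n = 4) in control and 9699 ± 4346 in transgenic samples, and the Y-linked genes Eif2s3y, Uty and Kdm5d stood at 0.68, 0.35 and 0.20 log2; 1 of 2 tested probe sets of Kdm5d had the opposite sign. The 5-prime to 3-prime ratio, a sign of RNA integrity, was 1.27 ± 0.0782 (SD, n = 4) in control and 1.28 ± 0.0949 in transgenic samples for Gapdh, and 0.588 ± 0.0547 and 0.579 ± 0.0737 for beta-actin, with exact permutation p of 0.971 and 0.8286 (adjusted p over 10 quality measures 0.971 each).

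**Figure D3:**
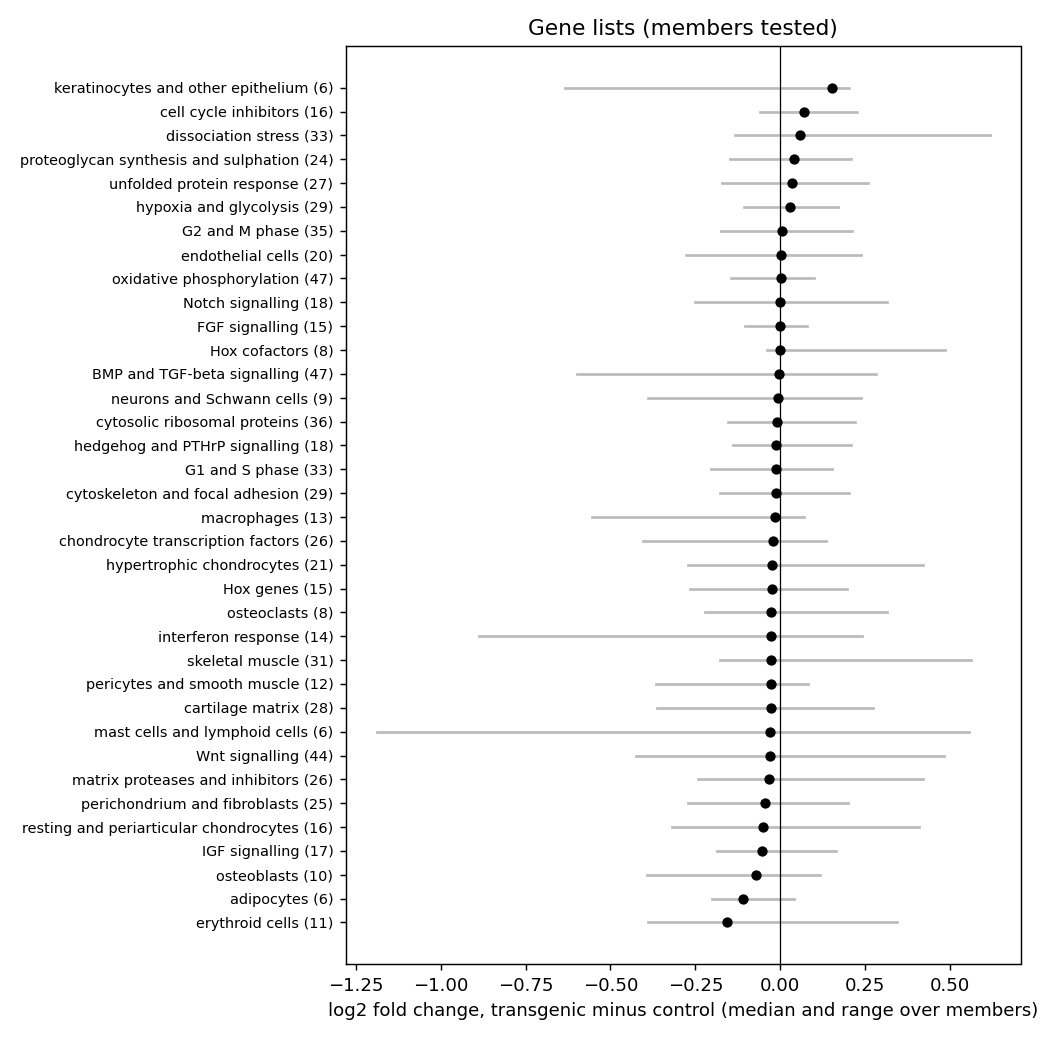
Median log2 fold change (points, transgenic minus control) and range over members (lines) of 36 gene lists, with the number of members tested in brackets. Medians lie between -0.16 for erythroid cells and 0.15 for keratinocytes and other epithelium.

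No member of any list passed over all genes tested, and 0 passed adjusted over the list alone. By camera 0 of the 36 lists passed, 3 had an unadjusted p under 0.05, and camera with an estimated correlation and fry gave 0 each; with litter as a block camera gave 3 and fry 0. The median, mean and test differed in sign for G1 and S phase, hedgehog and PTHrP signalling, Hox cofactors, skeletal muscle and osteoclasts. Leaving out single arrays moved the number of lists past the threshold to between 0 and 7, with 7 without transgenic replicate 4, 6 without control replicate 2, 2 without control replicate 3 or 4 and 1 without transgenic replicate 1 or 3.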

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

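Within each genotype, the gap of the highest or lowest of the 4 samples was set against the range of the group for 144 groups of values, and 10 samples stood apart by the 95% critical value, where chance gives about 7. The counts over splits of the samples, and the ratio of the counts with and without the litter, were chosen as tests after the results were seen; the fits with litter as a block and without single litters were planned. Il6 was highest in replicate 2 of both genotypes, 370.7 in control (next 156) and 460.7 in transgenic samples (next 262.7), and Cxcl1 was 1796 in control replicate 2 (next 826.1). The others were Acot8 at 271.9 in control replicate 3, Col2a1 at 45060 in transgenic replicate 2, Chsy1 at 5152 and Bmp2 at 1478 in control replicate 4, Ifitm5 at 227.1 in control replicate 2, Add2 at 64.08 in transgenic replicate 1 and Eif2s3y at 102 in control replicate 3.

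The genotypes gave fewer small p-values than the 1126 that even p-values would give. A candidate explanation is that differences between litters enter the spread when litter is left out, and with litter as a block the number of probe sets with an unadjusted p under 0.05 was 3.06 times as large (752 against 246). The 752 are still fewer than 1126. Of the 35 splits of the 8 samples into 4 and 4, 34 gave at least as many probe sets with an unadjusted p under 0.05 as the real one, 246, so that 246 is no excess over chance; 2, the real one included, gave as few, the lowest being 208. The highest other split gave 3903, sets litters 1 and 2 against litters 3 and 4, and points to a structure of the samples by litter. The real split gave 0 probe sets, genes and lists past the threshold, so that all 35 of the 35 splits had to give as many and the splits decide nothing about these counts; the highest other splits gave 46 probe sets, 28 genes and 19 lists. The other 7 splits that part every litter, as the real one does, gave 208 to 640 probe sets with unadjusted p under 0.05. Each remaining split of the 35 puts both samples of a litter on one side. With litter as a block, the same 7 splits gave 550 to 2024. The real 752 lies within that range, so no deficit is shown once the block is in the model.

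With litter as a block, 3 lists passed between genotypes, those of dissociation genes, erythroid cells and cell cycle inhibitors. Of the 8 splits that part every litter, 5, the real one included, gave at least 3 lists and the highest other gave 11, and 8 splits are too few for a share under 0.05. The 3 list calls were lost with an estimated correlation. With the block it was 0.217 for dissociation genes, 0.02 for erythroid cells and 0.034 for cell cycle inhibitors, against the preset 0.01. The last 2 lie near the preset value, so their loss does not show that members of these lists vary together. Each call was also lost without a single litter. This was litter 3 for dissociation genes (camera adjusted p = 0.502) and litter 1 for erythroid cells (0.213). For cell cycle inhibitors it was litter 1 (0.0843) or litter 3 (0.361).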

How the results depend on the processing

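Across 32 other fits, 0 probe sets and 0 genes passed the threshold by limma between genotypes, and Hoxc8 stayed positive and uncalled, between 0.05 and 0.23 log2; the smallest adjusted p of any probe set was 0.921. The number of probe sets with an unadjusted p under 0.05 ranged from 46 with the stricter filter to 1256 without a filter. The 66 other named genes gave 2066 values, of which 0 passed and 25, of 10 genes, had the opposite sign. List calls moved from 0 to 3 with the replicate block, 3 with the replicate block and Xist as a covariate (added after seeing the data) and 1 with array weights (erythroid cells, adjusted p = 0.00173), and stayed at 0 with the other offsets, filters, scalings and probe set rules, with eBayes without trend, with Xist alone, with estimated correlations and with fry. Besides these lists, and S100a8 and S100a9 when adjusted over their list alone, the replicate block changed no call. Leaving out one array or litter gave between 0 and 7 lists: 7 without transgenic replicate 4, 6 without control replicate 2, 2 without control replicate 3 or 4, and 1 without transgenic replicate 1 or 3 or without litter 1, 2 or 3; with the replicate block and without litters 1 to 4 in turn it gave 6, 4, 1 and 4. Leaving out a single array also unbalances the litters; the cause was not tested. Among these, cytosolic ribosomal proteins turned direction past the threshold without control replicate 2 (adjusted p = 0.0054, range 0.0054 to 0.908) and oxidative phosphorylation without transgenic replicate 4 (0.00311, range 0.00311 to 0.961). Camera was not run with the robust or unmoderated fits, which do not enter it. Signals near the array background limit the dim named genes.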

Other observations

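Many genes differed between litters. The tests in this part were chosen after the litter results were seen, except those of the covariates. By limma's F-test with genotype in the model, 2027 of 22519 probe sets and 1089 of 10989 genes differed between the 4 litters at an adjusted p of 0.05. The genes named here were chosen after their values were seen. Of the 36 lists, 16 held more such genes than the rest of the genes tested (one-sided Fisher's exact test). That test counts genes as independent, while members of a list can vary together across the 4 litters. Its p-values for lists can therefore be too small. Without a filter 995 probe sets differed and with the stricter filter 2305. The count thus depends on the filter, and lists of bright genes may be favoured, which was not tested. Cytl1, a secreted protein gene of cartilage, had mean signals of 5403, 2351, 12970 and 10400 in litters 1, 2, 3 and 4 (2 arrays each, adjusted p = 3.13e-05), and Wif1, a Wnt inhibitor gene, 647, 332, 1860 and 1161 (adjusted p = 3.13e-05). Genes of resting and periarticular chondrocytes differed in 9 of 16 cases (one-sided Fisher's exact test, adjusted p = 4.82e-05), among them Prg4, the lubricin gene (739, 384, 1461 and 1098), Gdf5, of the joint-forming region (250, 103, 566 and 314), and Tnc (3752, 2810, 6463 and 3766). Their list mean, centred over litters, was 0.01, -0.25, 0.36 and -0.11 log2. Markers of perichondrium and fibroblasts differed in 13 of 25 cases (adjusted p = 2.49e-06), with list means of 0.08, -0.17, 0.22 and -0.12 log2, and markers of mast and lymphoid cells in 4 of 6 (adjusted p = 0.00488), with -0.15, -1.05, 0.94 and 0.26 log2. The last depends on filter and offset: the values in litters 2 and 3 were -0.42 and 0.35 log2 without a filter, -1.54 and 1.22 with an offset of 1 and, in the reverse direction, 0.41 and -0.26 with the stricter filter. These 3 lists were lowest in litter 2 and highest in litter 3, also after quantile normalization and median centring, though litter 2 was the highest and litter 3 the lowest for the mast and lymphoid list with the stricter filter. The share of other cell types is thus not separated here from a change within chondrocytes. Of 31 skeletal muscle genes 9 differed (adjusted p = 0.00786), with Mylpf, a fast muscle myosin light chain gene, at 7169, 4057, 5188 and 9353. Among cartilage matrix genes 9 of 28 differed (adjusted p = 0.00486), and Sox9, the central transcription factor of chondrocytes, stood at 5270, 5392, 3527 and 3057 (adjusted p = 0.00101).

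Of 33 genes induced by dissociation, 28 differed between litters (Fisher's exact test, adjusted p = 2.96e-22). The estimated correlation within this list was 0.68 in the genotype fit without litter, so its genes do not count as independent and this p is too small. Atf3 had mean signals of 4308, 8040, 3605 and 2778 in litters 1, 2, 3 and 4, the heat shock gene Hspa1b 22730, 29190, 9993 and 15990, Zfp36 7025, 9881, 8939 and 4146 and Egr1 16320, 18050, 17830 and 9955. Of 27 genes of the unfolded protein response, 9 differed (adjusted p = 0.00413) and 6 of these were highest in litter 2, among them Ddit3 and Chac1 at 5495 and 2712; Eif2ak3, Dnajb11 and Pdia6 were highest in litters 3, 1 and 4. The metallothionein genes Mt1 and Mt2 were highest in litter 2, at 39450 and 32870. The mean of the dissociation list, centred over litters, was 0.03, 0.47, -0.05 and -0.46 log2, with the same order after quantile normalization and median centring. Without litter 2, 18 of the 33 genes differed, and without litter 4, 19; the number of probe sets that differed ranged from 562 to 3047 when single litters were left out.

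Chance pairing of the arrays is an unlikely source of the litter differences. Without a genotype term, the real pairing gave 2586 probe sets and the highest other gave 887. Of 100 pairings, 1, the real one, gave as many, which is the lowest share that 100 pairings can give. Several explanations were weighed for the stress genes. Sex composition, as read from Xist, is argued against, since 28 of the 28 genes still differed with Xist as a covariate. Litter stayed in the model, so this holds only for an effect that is the same within and between litters. Xist did vary within litters. Control and transgenic signals were 10060 and 6230 in litter 1 and 6091 and 14180 in litter 2. They were 13940 and 5726 in litter 3 and 11370 and 12660 in litter 4. With the mean of the muscle genes as a covariate 18 of 28 still differed and 22 kept an unadjusted p under 0.05. Over all probe sets the number went from 2027 to 1416. Litter stayed in that model, so the covariate was fitted from differences within litters, while the muscle list mean also varied between litters (0.13, -0.25, -0.10 and 0.21 log2). Skeletal muscle content is therefore not settled as a cause. RNA degradation stays open for litter 4, which had the lowest 5-prime to 3-prime ratio. With the ratio as a covariate 13 of 28 genes still differed and 23 kept an unadjusted p under 0.05. Over all probe sets the number that differed went from 2027 to 531. Litter stayed in this model as well. The log2 ratio differed within litters by 0.01, 0.0238, 0.014 and 0.0721, while the litter means were -0.189, -0.181, -0.0983 and -0.406. Ratio and litter thus overlap, which can lower these counts with or without degradation, so the counts do not decide the question. For litter 2 against litter 1 the ratio gave no sign of degradation, as the mean log2 ratios differed by 0.0077. This was less than the 0.0238 between arrays of a litter. Of the 28 genes, 27 were higher in both arrays of litter 2, but they had been chosen for differing between litters. The ratio rests on Gapdh and beta-actin only, so degradation is not excluded for these litters. Handling of a litter on its own day may be a source, and it cannot be told apart from a biological difference between litters, since the labels give no dates.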
